A study of Mus musculus with 4 samples.

How the data were processed

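RNA was measured in 2 libraries of cultured mouse B cells, 1 infected with the empty RVKM retrovirus and 1 with the virus carrying Ascl2. Total RNA was extracted with Trizol and libraries were made for sequencing by a commercial provider, per the labels' protocols. Groups were taken from the sample titles. The 2 chromatin samples of germinal centre B cells, taken from lymph nodes after KLH immunisation, were not analysed here.

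The deposited values are a signal per gene, an abundance scaled for sequencing depth and, as far as the values show, for gene length. The unit's name (FPKM or TPM) and the quantifier, gene annotation and strand setting are not given in the sources used here. The build mm10 and the tools Trim Galore, Bowtie2, Picard and MACS2 are named in the submitters' processing notes, with no versions and no statement of which served the RNA libraries. Each file listed the same 13792 Ensembl genes, none at 0, and every gene reached at least 0.475 in at least 1 library, so low genes appear to have been filtered before deposit. Of the identifiers, 13752 had a symbol in the reference tables. In the files, 20 symbols had been turned into dates. Identifiers were used to look up coordinates, but the symbols were left as they were, and gene lists were matched on these unchanged symbols. Coordinates are those of the reference annotation on GRCm38, the assembly called mm10.

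Because the values are not counts, no count model was used, and with 1 library per group no p-value was computed. Absolute depth is unknown. Among 1842 genes under 1.2 in both libraries, the ratio of low values clustered at 1.15 (35 genes, against a median of 9 in neighbouring intervals), which is read as the relative depth of the empty-vector library. Low genes are therefore slightly less precise in the Ascl2 library. Abundances are relative, so a gene group that takes a larger share of the total lowers the values of the rest.

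For each gene the log2 ratio was computed as log2 of the Ascl2 value plus 1 over the empty-vector value plus 1. Genes with a value of at least 1 in at least 1 library were kept (12283 genes), and a log2 ratio of at least 1 or at most −1 counted as 2-fold. Gene lists, 39 in all, were written from general knowledge before the data were examined. They cover Ascl2 biology, hypermutation and switching, B cell states, signalling, metabolism, stress and other cell types. A list was tested if at least 5 members passed the filter. Its median log2 ratio was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean log2 value, and percentiles up to 2.5 or from 97.5 counted as outside. This describes these 2 libraries and not the conditions. Many lists share genes. One gene is not reported here and was left out of the lists. The 3 rescalings below multiply the Ascl2 values by a factor of 0.03 to 0.05 on the log2 scale, which the pseudocount damps in low genes, so a median closer to 0 than 0.05 is not read as a direction. In 10 tested lists the median and the mean differed in sign, so the median is not read as a direction there. These were the lists of intestinal stem cell, homing, proneural, naive B cell, B cell receptor, antigen presentation, p53, cytokine, erythroid and stromal genes.

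The genes named were set by a rule fixed before the data were examined. It takes Ascl2, the gene in the virus, and the 12 highest and 12 lowest ratios among genes with a value of at least 5 in at least 1 library. Variable, diversity and joining segments and predicted or unnamed loci were left out there (6 among the highest, 11 among the lowest). From each list it takes up to 4 members with the largest ratios and any member past 2-fold. All members of the germinal centre, hypermutation and switching, B cell transcription factor, constant region and homing lists may also be named. Other genes named (Xbp1, Sdc1, Trim34a, Aida, Epha7 and Dennd6b) were chosen after their values were seen.

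Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter of 5, 3 rescalings of the Ascl2 library, thresholds of 1.5-fold and 3-fold, the list mean, and random lists without matching. Alternatives added after the data were seen were removal of the trend of the log2 ratio with genomic span (a running median over 501 genes ordered by span, known for 11579 of the kept genes), leaving out genes with more than 6 significant digits, and leaving out variable segments. The running median over span included the variable segments. The interval of a median over the genes of chromosome 7 came from 2000 bootstrap draws of genes. No check of GC content was made, because no genome sequence was used.

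The steps were tested on simulated data for this comparison with all 13792 genes. All 100 simulated 4-fold differences and 90 of 100 2.5-fold differences were found past 2-fold, as were 2 of 12091 unchanged genes. The simulated libraries held counting noise only, at an assumed depth, and differences were planted in genes with a value of at least 5. Variation between cultures or library preparations was not simulated, so these counts are not error rates for the real comparison. Of 100 random lists with no shift 4 lay outside the limits, and of 100 lists shifted by 0.4 on the log2 scale 98 did. The noise in these lists was independent between genes, so lists whose genes vary together were not covered. The planted shift of 0.4 was also larger than the median of any tested list with the main settings, the largest being 0.32. How often smaller shifts would be found was therefore not tested. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.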

Results

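The series measured RNA from mouse B cells and chromatin from germinal centre B cells. For the RNA libraries, naive B cells of C57BL/6 mice, a common inbred strain, were infected with a retrovirus and cultured with anti-IgM and anti-CD40 antibodies, which stand in for antigen and for T cell help. One virus carried no insert (RVKM-Empty, hereafter the empty vector) and the other carried Ascl2 (RVKM-Ascl2). Ascl2 is a basic helix-loop-helix transcription factor known from intestinal stem cells and T follicular helper cells. There was 1 library per group, so the values have no replicate error and no difference between the libraries has a replicate check. The 2 chromatin samples, an input and an Ascl2 immunoprecipitation, were not analysed here.

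Each library listed the same 13792 genes, as abundances scaled for depth. The values summed to 750692 in the empty-vector library and 763932 in the Ascl2 library, with medians of 10.2 and 10.2. A value of at least 1 was reached by 11869 genes with the empty vector and 11999 with Ascl2. Absolute depth is unknown, so no counting interval can be given. The steps between low values put the empty-vector library at about 1.15 times the depth of the Ascl2 library. Across genes, which are not independent replicates, the log2 values of the 2 libraries correlated with a Pearson r of 0.98. All log2 ratios are of the Ascl2 value plus 1 over the empty-vector value plus 1, which understates differences of low genes.

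The first comparison asked whether the library labelled Ascl2 carried the inserted gene. Ascl2 (ENSMUSG00000009248, chromosome 7, 142966822 to 142969264, mm10) was near the bottom of the range with the empty vector, at 0.0809, and reached 29.4 in the Ascl2 library. The log2 ratio was 4.81, and it ranged from 2.76 to 7.35 with larger or smaller pseudocounts because the empty-vector value is so low. The direction goes with the labels.

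The main comparison asked which genes differ when Ascl2 is introduced. Of 12283 genes with a value of at least 1 in either library, 188 were at least 2-fold higher in the Ascl2 library and 88 were at least 2-fold lower, while 12007 lay between. For scale, 90.7% differed by less than 1.5-fold. Immunoglobulin variable segments made up 87 of the higher genes and 2 of the lower ones. Among the 12062 other genes, 101 were higher and 86 lower. The log2 ratio was related to the genomic span of a gene, with a Spearman rho of 0.19 across genes. With that trend removed the counts were 142 higher and 107 lower. Both the rho and the trend include the variable segments, so the removal can take away part of their own rise. The change in the counts is therefore not read as an effect of span.

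**Figure D1:**
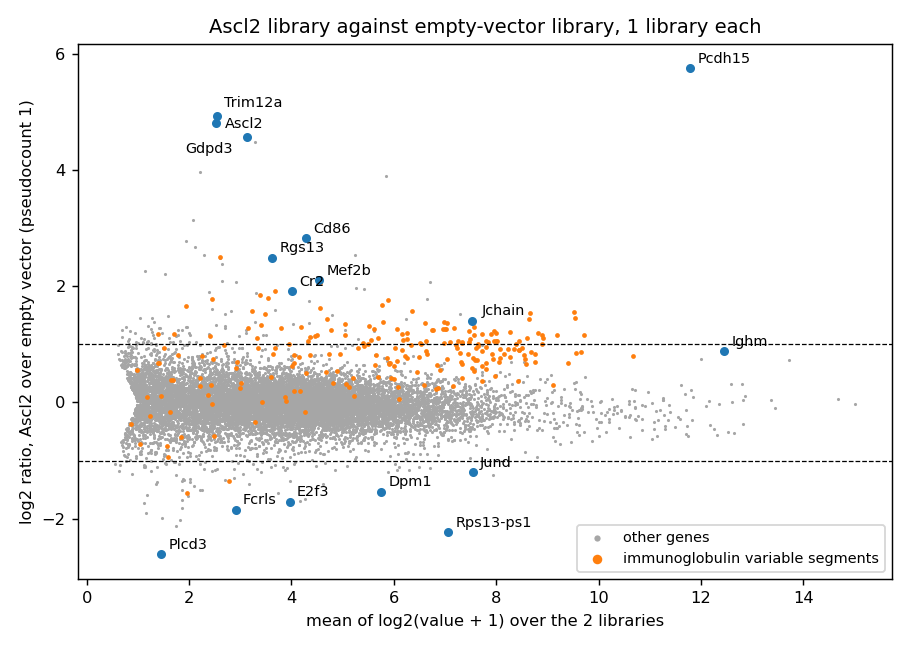
Log2 ratio of the Ascl2 library over the empty-vector library (vertical axis) against the mean of log2(value + 1) over the 2 libraries (horizontal axis); each point is 1 of 12283 genes, orange points are immunoglobulin variable segments, blue points are labelled genes and dashed lines mark 2-fold. Ascl2 lies at 4.81 and Cd86 at 2.83, and most variable segments lie above 0.

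The 12 named genes with the highest ratios were of mixed function. Cd86, a costimulatory ligand for T cells, was 6.29 with the empty vector and 50.8 with Ascl2 (log2 ratio 2.83). Rgs13, a regulator of G protein signalling in germinal centre B cells, was 4.21 and 28.3 (2.49). Smo, the signal transducer of the Hedgehog pathway, was 1.03 and 10.8, and Sh3gl2, an endocytic adaptor, was 1.56 and 13.4. Rgs13, Smo and Sh3gl2 are among 7 genes whose deposited values carry more than 6 significant digits, and all 7 were at least 2-fold higher with Ascl2. Whether these 7 values were made like the others is not known. The histone demethylase gene Kdm4c was 1.73 and 13.2.

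Pcdh15, a protocadherin known from sensory hair cells, was 481 with the empty vector and 26003 with Ascl2 (log2 ratio 5.75). This was the highest ratio with a pseudocount of 1, while with 0.1 Trim12a (7.67) and Ascl2 (7.35) lay above it (5.76). Its share of the summed values was 0.0641% and 3.40%. For scale, the largest value of any gene in the Ascl2 library was 32937, and Igkc, the kappa light chain constant region, was 17438 there. Whether the Pcdh15 values come from its own transcript or from reads of another source was not tested. Gdpd3, a glycerophosphodiester phosphodiesterase gene, was 0.793 and 41.8 (4.58). Trim12a, Trim30d and Trim5, tripartite motif genes that neighbour one another on chromosome 7, had values of 0.0535, 0.709 and 0.344 with the empty vector and 31.2, 9.99 and 5.20 with Ascl2. These Trim genes are paralogs, and how reads were split between them is uncertain. The same holds for Rbpsuh-rs3, a copy related to the Notch pathway gene Rbpj, at 0.464 and 9.09.

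The 12 named genes with the lowest ratios were of mixed function. Plcd3, a phospholipase C gene, was 5.82 with the empty vector and 0.112 with Ascl2 (log2 ratio −2.62). The scavenger receptor gene Fcrls was 13.2 and 2.96 (−1.84), and Lyplal1, a lysophospholipase-like gene, was 5.83 and 0.951 (−1.81). E2f3, a transcription factor of the cell cycle, was 27.3 and 7.65 (−1.71), and Dpm1, part of dolichol-phosphate mannose synthase, was 90.6 and 30.5 (−1.54). Ssbp4, a single-stranded DNA binding protein gene, was 39.1 and 14.1 (−1.41). The remaining 6 share sequence with near-identical copies and are uncertain. They are the ribosomal protein pseudogenes Rps13-ps1 (290 and 61.0) and Rpl35a-ps4 (6.15 and 0.757), the signal recognition particle RNA genes Rn7s1 (31.0 and 8.94) and Rn7s6 (5.91 and 1.27), and the histone genes Hist1h2ah (13.7 and 4.53) and Hist1h4c (24.1 and 8.85).

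Genes of the machinery for somatic hypermutation and class switching, taken here as uracil repair, mismatch repair, end joining and their cofactors, mostly had similar values in both libraries. Of 37 measured, Hmces was at least 2-fold higher with Ascl2, none was at least 2-fold lower, and 36 lay between. Hmces, which shields abasic sites, was low in both libraries, at 0.493 with the empty vector and 2.18 with Ascl2. The uracil glycosylase gene Ung was 21.6 and 13.7, and the DNA damage kinase gene Atm was 9.03 and 12.4. The list's median log2 ratio of 0.06 lay at percentile 94.0 of 10000 random lists matched on expression, inside their central 95%.

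Of 29 measured transcription factors that act in activated B cells, Prdm1 was at least 2-fold higher with Ascl2 and the other 28 lay between the limits. Prdm1, which encodes the plasma cell regulator Blimp-1, was 3.10 with the empty vector and 9.23 with Ascl2 (log2 ratio 1.32). Bach2, which counteracts Prdm1, was 7.06 and 12.995, short of 2-fold. Pax5, which holds B cell identity, was 98.4 and 97.7, Irf4 was 88.3 and 108.2, Batf was 179 and 115, and the E protein gene Tcf3 was 113 and 80.7. The E protein inhibitor Id3 was 16.3 and 10.4. The list's median log2 ratio of −0.10 lay at percentile 19.985.

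Germinal centre genes were higher as a group in the Ascl2 library with the main settings, but not in every later check. Of 34 measured, 22 had a log2 ratio above 0, 3 were at least 2-fold higher and none was at least 2-fold lower. The 3 were Cd86, Rgs13 and Mef2b, a transcription factor gene of germinal centre B cells that was 10.2 with the empty vector and 47.3 with Ascl2 (log2 ratio 2.10). Rgs13 is one of the 7 genes with extra digits. Without it the list lay at percentile 99.5, but leaving out 1 of 34 genes can hardly move a median. Without its 3 members past 2-fold the list's median was 0.06 at percentile 95.3, inside the central 95%. That removal was chosen after the data were seen and by its construction lowers the median. Mybl1, another transcription factor gene of germinal centre B cells, was 3.69 and 6.43. Bcl6, the master regulator of the germinal centre, was 12.2 and 9.36, and Fas was 82.2 and 85.7. The list's median of 0.12 lay at percentile 99.5 of matched random lists. With the gene-span trend removed the median was 0.06 at percentile 90.8, inside the central 95%. The list mean, which the 3 members past 2-fold raise, was 0.30 at percentile 99.96. Myeloid marker genes, a check for other cells, had a median of 0.21 at percentile 97.1 in the same libraries. That median was 0.12 with a filter of 5 and 0.10 with a pseudocount of 5, and 12 of the 15 members reached a value of 1 with the empty vector.

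**Figure D2:**
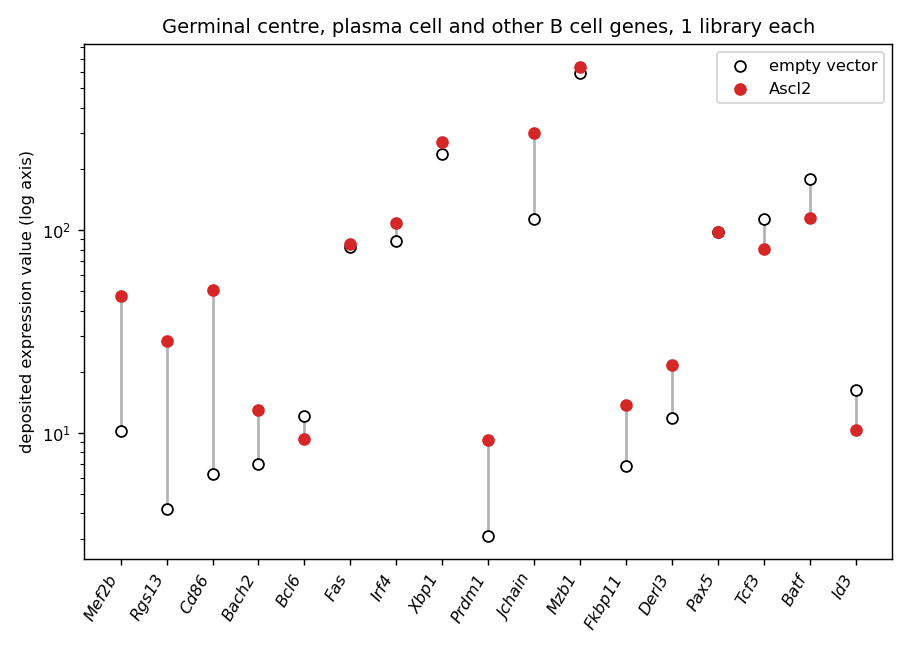
Deposited values on a logarithmic axis in the empty-vector and Ascl2 libraries for selected B cell genes; each point is 1 library and there are no replicates. Cd86 was 6.29 and 50.8, and Jchain was 113 and 301.2.

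Plasma cell genes were higher as a group, in 18 of 21 measured members. Jchain, which joins IgM and IgA into polymers, was 113 with the empty vector and 301.2 with Ascl2 (log2 ratio 1.41), and Prdm1 was the other member past 2-fold. Fkbp11 was 6.89 and 13.7, and Derl3, part of endoplasmic reticulum quality control, was 11.9 and 21.6. Xbp1, which drives the secretory programme, was 238 and 272, and the surface marker Sdc1 was 2.99 and 2.37. The median log2 ratio of 0.25 lay at percentile 99.99, where the central 95% of random lists ran from −0.20 to 0.11. The myeloid median of 0.21 stands beside this result too.

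Genes of the unfolded protein response were slightly higher as a group. None of the 26 measured was past 2-fold, and 18 had a ratio above 0. The chaperone gene Dnajb9 was 15.3 with the empty vector and 25.8 with Ascl2, Edem1 was 41.1 and 64.2, and Ddit3 was 42.0 and 62.7. The median of 0.10 lay at percentile 98.6, and at 93.8 when the mean replaced the median and 95.04 when random lists were not matched on expression. With the gene-span trend removed the median was 0.19 at percentile 99.9, where the myeloid list also lay above the range, at 99.1. The myeloid median of 0.21 at percentile 97.1 stands beside this result as well.

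Immunoglobulin transcripts took 5.50% of the summed values with the empty vector and 9.52% with Ascl2. Among 12 constant region and joining chain genes, Jchain alone was past 2-fold. Ighm, the constant region of IgM, was 4124 and 7629 (log2 ratio 0.89), and Igkc, that of the kappa light chain, was 10479 and 17438 (0.73). Ighg1, the constant region of the switched isotype IgG1, was 1189 and 946, Ighg3 was 54.4 and 80.1, and Ighe was 158 and 181. The list's median of 0.32 lay at percentile 99.8, and at percentile 97.4 with the gene-span trend removed, just inside the central 95%. That trend was computed with the variable segments included, so it can hold part of the immunoglobulin rise. Its removal is therefore no independent check of this list. The myeloid median of 0.21 applies to this list as well.

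The variable segments were higher across all 3 loci. Of 221 measured segments, 87 were at least 2-fold higher, 2 were at least 2-fold lower, and 94.1% had a log2 ratio above 0, with a median of 0.87. The summed values were 1.94 times as high with Ascl2 for 113 heavy chain segments, 1.86 times for 105 kappa segments and 2.77 times for 3 lambda segments. The lambda constant region genes differed less. With the empty vector and with Ascl2, Iglc1 was 733 and 996, Iglc2 was 591 and 697, and Iglc3 was 1126 and 988. Segments of one family share sequence, so single segments are not named.

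**Figure D3:**
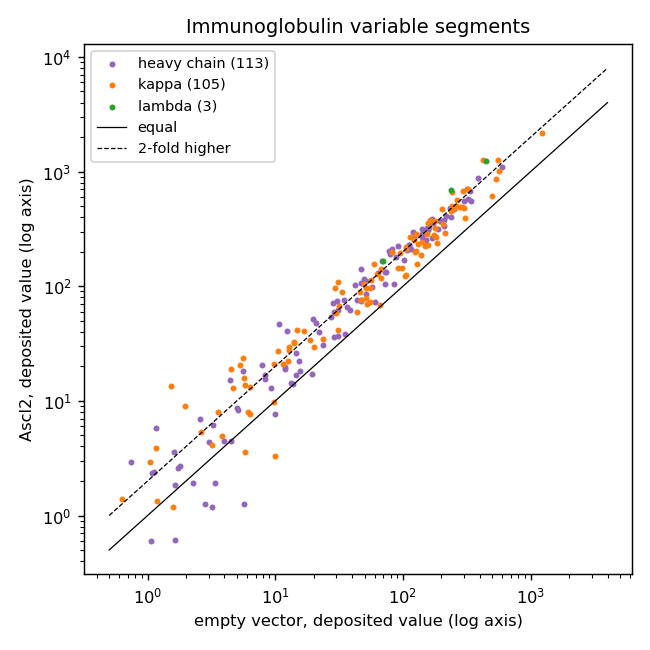
Deposited value in the Ascl2 library (vertical) against the empty-vector library (horizontal), both on logarithmic axes, for 113 heavy chain, 105 kappa and 3 lambda variable segments; each point is 1 segment, the solid line marks equal values and the dashed line 2-fold higher with Ascl2. Most points lie above the line of equal values, with median log2 ratios of 0.84, 0.90 and 1.46 for the 3 loci.

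Immediate early genes, which respond within minutes to stimulation or handling, were lower as a group in the Ascl2 library. Their list also holds heat shock chaperone genes. Of 19 measured, 16 had a ratio below 0 and only Jund was past 2-fold, at 281 with the empty vector and 121 with Ascl2 (log2 ratio −1.21). Junb was 250 and 129, Ier2 was 103 and 57.0, and Klf2 was 33.9 and 18.6. The median of −0.28 lay at percentile 0.12 of matched random lists. With the gene-span trend removed the median was −0.12 at percentile 6.73, inside the central 95%.

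In all, 36 lists fixed before the data were examined had at least 5 measured members. Of these, 4 lay above the central 95% of random lists and 1 below. If the members of a list varied independently, 1.8 would be outside by chance. Genes of 1 list can vary together and several lists share members, so these counts are not read as an excess over chance. Lists of other B cell states lay inside. Naive B cell genes (median −0.06, percentile 42.3) included Cr2, a complement receptor gene at 7.35 with the empty vector and 30.5 with Ascl2, and Ets1 at 10.04 and 36.2. Marginal zone and B-1 cell genes (0.10, percentile 92.2) included the scavenger receptor gene Cd36 at 4.30 and 10.7. B cell activation genes (−0.09, percentile 25.5) had 1 member past 2-fold, Cd86, while Egr2 was 125 and 72.4. Genes of B cell receptor signalling (−0.03, percentile 65.9) and of antigen presentation (−0.02, percentile 65.4) had Cr2 and again Cd86, respectively, as their only members past 2-fold.

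Gene groups known from Ascl2 in other tissues also lay inside. The intestinal stem cell list (median −0.06, percentile 27.8) had 1 of 11 members past 2-fold, the transcription factor gene Ets2, at 2.68 with the empty vector and 14.6 with Ascl2. Ets2 is another of the 7 genes with extra digits, of which it is not known whether they were made like the others. None of 16 homing genes studied in T follicular helper cells was past 2-fold (median −0.05, percentile 39.8). Cxcr5, the follicular homing receptor, was 83.0 and 74.0, Cxcr4 was 40.0 and 49.8, and the integrin gene Itga4 was 7.97 and 13.9. Targets of proneural factors (−0.03, percentile 39.9), basic helix-loop-helix and Id genes (−0.15, percentile 10.8), and Notch and Wnt genes (−0.07, percentile 18.6) had no member past 2-fold. The largest ratios in the last group were those of Lef1, at 52.3 and 26.03, and Hes1, at 0.879 and 2.53. With the gene-span trend removed the median of basic helix-loop-helix and Id genes was 0.002 at percentile 57.1.

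Growth and metabolism lists lay inside, with no member past 2-fold, though 4 of them went below the range under another setting. Myc targets of ribosome biogenesis lay nearest to the limit, with a median of −0.17 at percentile 2.74, and below it at 0.30 by the list mean. Srm, a polyamine synthesis gene, was 86.6 with the empty vector and 51.7 with Ascl2, and the nucleolar gene Fbl was 92.5 and 59.4. Genes of the G1/S transition had a median of −0.16 at percentile 4.98 (1.91 without matching on expression), and those of G2/M −0.02 at percentile 73.8. Glycolysis (−0.12, percentile 16.7), oxidative phosphorylation (−0.14, percentile 15.98, or 0.81 by the list mean) and cholesterol synthesis (−0.10, percentile 28.1) were also inside. So were chromatin modifiers (0.02, percentile 77.5), ribosomal proteins (−0.15, percentile 11.7, or 0.35 by the list mean and 2.3 without matching), mitochondrially encoded genes (0.07, percentile 89.5) and housekeeping genes (−0.08, percentile 38.5). With the gene-span trend removed the ribosomal protein median was 0.01 at percentile 54.1.

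Among lists of markers of other cell types, the myeloid list was nearest to a limit. Fcer1g was 5.71 with the empty vector and 9.83 with Ascl2, Vcan was 0.0941 and 1.40, and Cd68 went the other way at 16.2 and 10.8. Mast cell and basophil genes (median 0.26, percentile 90.9), erythroid and platelet genes (0.22, percentile 77.9), T cell genes (−0.19, percentile 14.1), dendritic cell genes (−0.04, percentile 44.0), and stromal and packaging-line genes (−0.15, percentile 22.1) lay inside. Few members of these lists passed the filter: 5 of 23 T cell genes, 7 of 15 dendritic cell genes and 5 of 26 stromal and packaging-line genes. Several that did had values above the library medians of 10.2. Among them were Thy1 (395 and 346.1), Lck (21.7 and 17.8) and Cd2 (16.6 and 19.6) of the T cell list. Batf3 of the dendritic cell list (22.9 and 18.4) and Vim of the stromal list (223 and 176) were others. Whether these values came from other cells or from the B cells themselves was not tested. Natural killer, neutrophil and sex-linked genes had too few members, with 3, 3 and 4 measured and medians of 0.37, 0.13 and 0.34. The 4 sex-linked members, all on the Y chromosome, were present in both libraries and higher with Ascl2, none by 2-fold. Ddx3y and Uty were at 18.2 and 8.31 with the empty vector and 23.4 and 13.4 with Ascl2. Eif2s3y and Kdm5d were at 90.7 and 14.2 with the empty vector and 112 and 18.1 with Ascl2. The source of this difference was not tested.

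**Figure D4:**
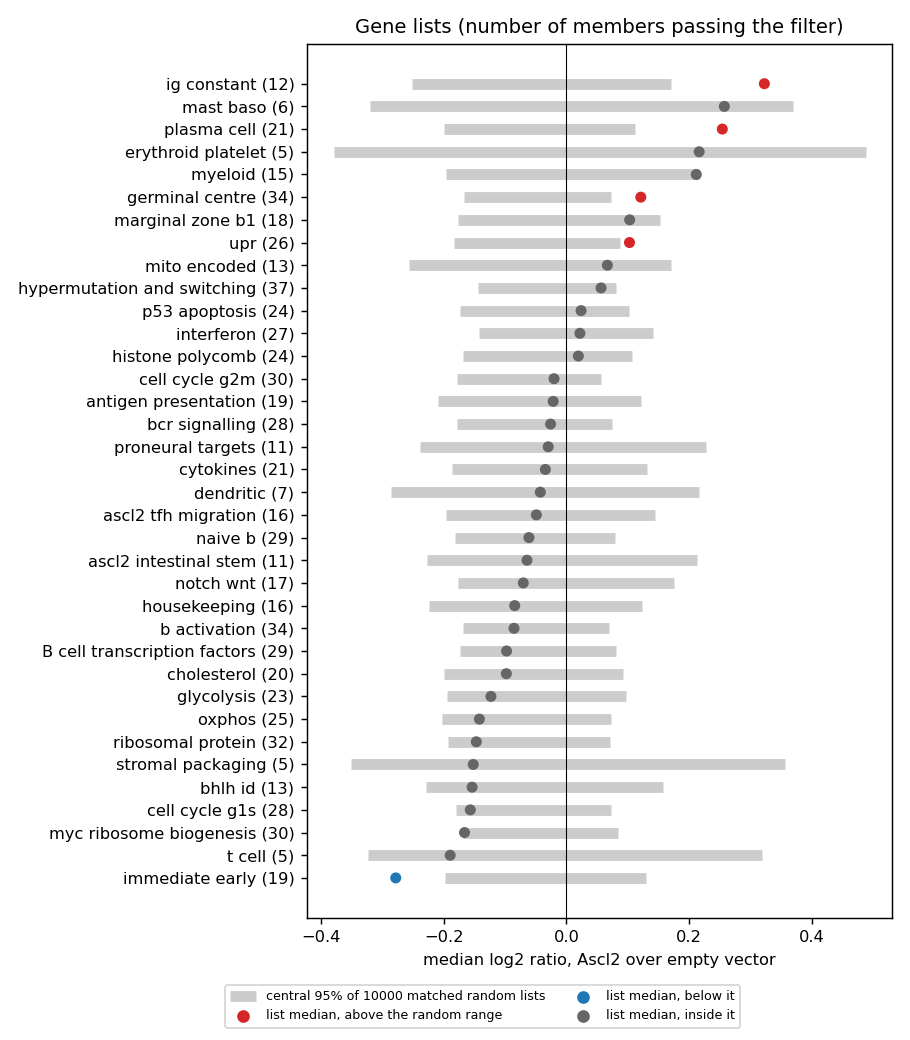
Median log2 ratio of each gene list (points) and the central 95% of 10000 expression-matched random lists of the same size (grey bars), with the number of measured members in parentheses. Red points (4 lists) lie above the random range and the blue point (1 list) below.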

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

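The tests with the gene-span trend removed, without variable segments and without genes of extra digits were chosen after the results were seen. No paired analysis was possible because each group holds 1 library, and for the same reason no replicate could be left out. Counts of higher and lower genes were 370 and 220 with a pseudocount of 0.1, 103 and 20 with 5, 615 and 530 at 1.5-fold, and 41 and 15 at 3-fold, against 188 and 88. These follow from the construction of each setting. Without variable segments 101 genes were higher. The 3 rescalings gave 204 to 208 higher and 78 to 85 lower. The log2 ratio of Ascl2 was 7.35 and 2.76 with pseudocounts of 0.1 and 5, 4.84, 4.86 and 4.86 under the rescalings by median, upper quartile and sum, and 4.997 with the span trend removed. All 227 values of the genes named by rank kept their direction, and 222 stayed past 2-fold. The other 5, under a pseudocount of 5, were Trim5, Rpl35a-ps4, Lyplal1, Rn7s6 and Hist1h2ah. A pseudocount or filter cannot turn the sign of a ratio, and the rescalings shift it by at most 0.05. The kept direction is therefore no check in those settings. Lists outside the random range numbered 8 without matching and 3 with the span trend removed, against 5, and the cause was not tested. Of 428 list values, 16 crossed a limit. The plasma cell list crossed none. The Myc list went below with a pseudocount of 5 (percentile 2.03), a filter of 5 (2.35), the mean (0.30) and no matching (1.2). The myeloid list went above with no filter (98.1), no matching (98.9) and the span trend removed (99.1), while its median was 0.12 at percentile 88.3 with a filter of 5 and 0.10 at 94.2 with a pseudocount of 5, against 0.21 at 97.1. Below the range went oxidative phosphorylation (0.81) and ribosomal proteins (0.35) by the mean, and ribosomal proteins (2.3) and G1/S genes (1.91) without matching. With the span trend removed the ribosomal protein median was 0.01 at percentile 54.1, against −0.15 at 11.7. The unfolded protein response list came inside by the mean (93.8) and without matching (95.04). With the span trend removed the germinal centre (90.8), constant region (97.4) and immediate early (6.73) lists came inside. For the constant region list this is no independent check, because the trend was computed with the variable segments included. Unknown depth limits all values near 1.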

Other observations

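The tests of clones, of antibody-secreting cells, of reads shared between Trim genes and of the median over chromosome 7 were chosen after the results were seen, as was the removal of the gene-span trend as an alternative. Cytokine and receptor genes lay inside the random range as a list (median −0.03, percentile 46.6). Its only member past 2-fold was Il10, the anti-inflammatory cytokine gene, at 4.63 with the empty vector and 12.3 with Ascl2. Tgfb1 went the other way, at 70.5 and 43.1, and the growth factor gene Csf1 was 19.0 and 12.7. Il1b was 1.13 and 2.01. Interferon response genes (median 0.02, percentile 62.5) had no member past 2-fold among 27, with Mx2 at 1.94 and 1.22 and Ifi203 at 74.5 and 98.4.

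The p53 and apoptosis list had a median of 0.02 at percentile 80.5 and a mean of −0.11, with no member past 2-fold among 24. The death effector gene Bax was 142 with the empty vector and 83.9 with Ascl2, and Phlda3 was 21.9 and 12.7. Aen was 27.8 and 17.7, while Trp53inp1 was 19.5 and 33.3. Replication-dependent histone genes, a group formed after the data were seen, had a median log2 ratio of −0.36 over 53 genes, of which 8 were at least 2-fold lower and none higher. Their summed values were 1112 and 1064.

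Immunoglobulin variable segments were higher in the Ascl2 library, with a median log2 ratio of 0.87. A few expanded clones would raise a small number of segments, while the rise was spread, with 94.1% of 221 segments above 0. This restates the pattern, because a median of 0.87 already puts most segments above 0. Segments of 1 family also share sequence, so reads of 1 clone may be counted on several. The share therefore cannot decide for or against clones. A larger share of antibody-secreting cells cannot be told apart: the plasma cell list without Jchain lay at percentile 99.98, but this restates the percentile of the whole list, all 21 of its measured members were also at 1 or more with the empty vector, and 9 belong to another list. Among abundant genes of such cells, Igkc was 10479 and 17438 and Jchain 113 and 301.2, while Sdc1 was 2.99 and 2.37, and no sort removing these cells is described in the labels. Whether Ascl2 acts within each cell, changes the mix of cells, or neither, was not tested and stays open with 1 library per group.

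The list of immediate early genes, which also holds heat shock chaperone genes, was lower in the Ascl2 library, at percentile 0.12 of random lists. Among genes grouped by genomic span, the median log2 ratio ran from −0.16 in a group of short genes (median span 4216 bases) to 0.08 in a group of long ones (72954 bases). These were not the ends of the order. The shortest group (990 bases) had a median of −0.07 and the longest (146619 bases) a median of 0.06. Variable segments were included in the groups. With this trend removed the list lay at percentile 6.73 with a median of −0.12, where random lists ran from −0.15 to 0.15, and before it was −0.28 against −0.20 to 0.13. A technical difference linked to gene length could therefore account for part of the pattern, though the direction stayed. The origin of the trend, in RNA handling, library preparation or the cells, was not tested.

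Of 7 neighbouring Trim genes on chromosome 7 (104244448 to 104507853), 4 were at least 2-fold higher with Ascl2, including Trim34a at 3.18 and 9.16. If reads had only moved between these paralogs, their sum would be level, but it was 47.9 and 108, a log2 ratio of 1.16 where the central 95% of 11221 other windows of 7 genes ran from −0.45 to 0.33. A rise shared by most of the chromosome would lift the median of its 891 genes, but this was −0.10 (bootstrap 95% interval over genes −0.12 to −0.06), against −0.01 for the median of the other 19 chromosomes. A difference that leaves the median in place cannot be told apart, since the share of genes at least 2-fold higher was 1.35% (0.905% without the Trim genes), above the others' median of 0.525% and below their highest value of 1.96%. A strain difference between the donor mice was not tested, nor was an effect of Ascl2.

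Besides Rgs13, Smo, Sh3gl2 and Ets2, the genes whose values carry more than 6 significant digits were Aida (44.8 and 123.6), Epha7 and Dennd6b, with log2 ratios of 1.45, 1.61 and 2.09, and without all 7 of them 181 genes were at least 2-fold higher.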
